A study of Drosophila melanogaster with 10 samples.

How the data were processed

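Total RNA was taken from 2 tissues of Drosophila melanogaster kept at 25 °C. The notum part of wing discs came from wandering larvae and holds the precursors of the adult muscles together with disc epithelium. Flight muscle came from pharate animals about 96 h after puparium formation. All animals carried Mef2-Gal4, which drives transgenes in the muscle lineage, and UAS-Dicer2, which strengthens RNA interference. The control, labelled WT, carried an mCherry hairpin, and the other genotype, labelled Rbf-KD, a hairpin against Rbf. The hairpins sit on transgenes from different sources, so each comparison also holds whatever else differed between the stocks. There were 3 libraries per genotype for notum and 2 per genotype for flight muscle, 10 in all.

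Per the labels' protocols, ribosomal RNA was depleted with Ribo-Zero and libraries were made with a stranded TruSeq kit. The deposited table holds raw counts for 29173 transcripts, with no normalization. Per the submitters' processing notes, bcl2fastq 2.17.1.14, FastQC, TopHat2 2.1.1, Bowtie2 2.3.2, Subread, featureCounts and DESeq2 1.14.1 were used with genome build BDGP5. The annotation version, the strand setting and the treatment of reads shared between features were not given in the sources used here. The deposited counts show that a read was counted in each transcript it overlapped, since isoforms of a gene hold nearly equal counts. Genes lying inside an exon of another gene on the same strand had the same read density as their host (median ratio 1.0 over 204 pairs). Genes on the opposite strand came close to that (0.9475 over 26 pairs), so strand was apparently not used in counting. Reads of overlapping genes can then not be told apart, and such genes are reported as uncertain.

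Transcripts were matched to genes by identifier in the BDGP6 annotation. In all, 27011 transcripts (92.6%) matched 15259 genes, of which 13372 are protein-coding. The 2162 unmatched transcripts held between 9.86% and 20.34% of the counts of a library and stayed out of the gene tests. Only chromosome arms are given, because the annotation and the counts use different builds. A gene's count was that of its transcript with the highest total, which avoids counting a read several times. A count of 0 in a library allows up to 3 counts, which is between 0.0409 and 0.0713 CPM (counts scaled to a library total of 1e6). Such limits and the 95% intervals of count ratios cover counting error only, since reads carried no molecular identifiers.

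Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and tested with the robust quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. There were 4 comparisons. The genotypes were compared within notum (3 against 3) and within flight muscle (2 against 2), each fitted on its own libraries. WT flight muscle was compared with WT notum, and the effect of genotype was compared between the tissues, both in a fit of all 10 libraries with a 4-level group. Adjusted p-values of single genes are from edgeR unless DESeq2 or limma-voom is named as the test. CPM values are TMM-scaled within the fit they come from.

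Gene lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, with adjustment over the lists of a comparison. The same test was run with the correlation estimated from the data. It then also uses the residual degrees of freedom of the fit, which were 4 in notum, 2 in flight muscle and 6 in the other comparisons. In flight muscle no list passed it (lowest adjusted p = 0.221), also where the estimated correlation was negative (Fat body, -0.067). A loss there can therefore not be put down to correlation between genes alone. The lists were Rb/E2F and dREAM components, DNA replication, Mitosis, DNA repair, Ribosome biogenesis, Apoptosis, Sarcomere, Myogenic regulators, Myoblast fusion, Oxidative phosphorylation, Glycolysis, TCA cycle, Germline genes, Ecdysone response, Heat shock and Antimicrobial peptides. Markers of other cells or states were Disc epithelium, Tracheal cells, Hemocytes, Fat body, Neurons, Glia, Tendon cells, Cuticle and pigment, Adult muscle precursors and Sex markers. The listed genes Strn-Mlck, lms, vas, nos and dys had no match and were not analysed here. Lists, designs, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Rbf, E2f1, E2f2, Dp, Mef2 and Dcr-2. It also names the 6 highest and the 6 lowest fold changes among called protein-coding genes with a proper name, a mean of at least 5 CPM and no overlap between the groups. For a list that passed it names 2 or 3 members of smallest adjusted p in the direction of the list. For other lists it names at most 2, and for the difference between tissues the 4 of smallest adjusted p each way. Genes outside the rule are said to be so. The flight muscle value of 1 gene named by the rule is not reported here.

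Before averaging, libraries of a group were compared. No pair was within sampling noise (chi-square per gene from 17.1 to 204, Spearman correlation across genes from 0.975 to 0.997). Nothing in the labels says that libraries came from separate animals or batches, so p-values that compare libraries measure only the spread between these samples, which may be technical. Those of camera at the preset correlation compare genes with genes. They rest on the assumed correlation of 0.01 and do not measure the spread between libraries. The estimated correlation reached 0.949 for Glycolysis in flight muscle. In notum, libraries with the same replicate number deviated together from their group means (correlations of 0.698, 0.615 and 0.225). So did WT 2 with Rbf-KD 3 (0.532) and WT 3 with Rbf-KD 2 (0.169). Correlations of a replicate 1 library with another number were negative (-0.234 to -0.694). The labels do not say what the numbers mark. The main test was left unblocked, same-numbered libraries are called pairs, and a replicate block was an alternative. A blocked value is printed where it changes a call or moves a count by over 1.5 times. In flight muscle the correlation of same-numbered libraries was -0.217.

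The alternatives were DESeq2 size factors, the library total alone, scaling without the 1% most abundant genes or without rRNA and mitochondrial genes, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, a fit of all 10 libraries or of the WT libraries alone, an absolute log2 fold change over 1, each library left out in turn, and fry for lists. The sum over transcripts, unmatched transcripts added, both replicate 1 notum libraries left out, a crossed block in flight muscle, and genes of identical counts taken as 1 in the overlap of tissues were added after seeing the data. The steps were tested on simulated data with 200 changed genes. Of genes changed by 1 and by 2 on the log2 scale, edgeR recovered 63% and 84% in the notum design (12203 genes, 11 false calls). It recovered 16% and 81% in the flight muscle design (10930 genes, 17 false calls). The corresponding values were 51% and 85% for the stage design (13407 genes, 4 false calls) and 18% and 71% for the difference between tissues (13407 genes, 3 false calls). In the same order DESeq2 made 54, 53, 27 and 51 false calls. It recovered 87%, 65.5%, 82.5% and 68% of all 200 changed genes. In these simulations edgeR called 158, 114, 140 and 92 genes. Its false calls in the notum and flight muscle designs thus exceeded a share of 0.05.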

Results

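RNA was sequenced from the notum part of the larval wing disc, which holds the adult muscle precursors, and from flight muscle of pharate animals about 96 h after puparium formation. In each tissue a control labelled WT was set against animals labelled Rbf-KD, in which Mef2-Gal4 drove a hairpin against Rbf, the fly retinoblastoma-family protein that represses E2F target genes. Notum had 3 libraries per genotype and flight muscle 2. Gene counts summed to between 42097050 and 55401980 per notum library and between 53864590 and 73408335 per flight muscle library. The composition of the flight muscle libraries differed by genotype. The 1% most abundant genes took 76.7% and 76.7% of the counts in the WT libraries and 63.5% and 64.1% in those labelled Rbf-KD, and mitochondrial genes took 22.4% and 20.17% against 16.1% and 16.81%.

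The targeted gene was examined first in every library. In flight muscle, Rbf (FBgn0015799, chromosome X) had 187 and 203 counts in WT and 1210 and 1454 counts in the libraries labelled Rbf-KD. On the TMM scale this was 5.16 ± 0.656 CPM (mean ± SD, n = 2) against 14.4 ± 0.720 CPM (n = 2), a log2 fold change of 1.48 (SE 0.17, edgeR adjusted p = 0.00229). The Rbf count therefore went against the label in flight muscle, and the libraries are called by their labels throughout. In notum, Rbf had 4346, 5179 and 4643 counts in WT and 4025, 4081 and 4336 counts in the libraries labelled Rbf-KD. The log2 fold change was -0.25 (SE 0.18, edgeR adjusted p = 1.00, unadjusted p = 0.202), and a knockdown of the mRNA was not detectable against the spread between libraries. The effect on Rbf differed between the tissues (log2 1.76, SE 0.29, edgeR adjusted p = 0.00188). RNA of disc epithelium may hide a change of Rbf in the notum precursors. Rbf is represented by 1 transcript, so the counts do not separate parts of the gene. Dcr-2, which the driver also expressed, was at 32357 ± 5760 CPM in WT muscle (n = 2) and on the TMM scale did not differ by the test between genotypes in either tissue. Its log2 fold change was -0.08 in notum and -0.21 in flight muscle (edgeR adjusted p = 0.325), and in flight muscle became 0.90 under library-total scaling, where it passed (adjusted p = 0.00567). Dcr-2 overlaps Rab4 on the other strand, and its counts are uncertain.

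**Figure D1:**
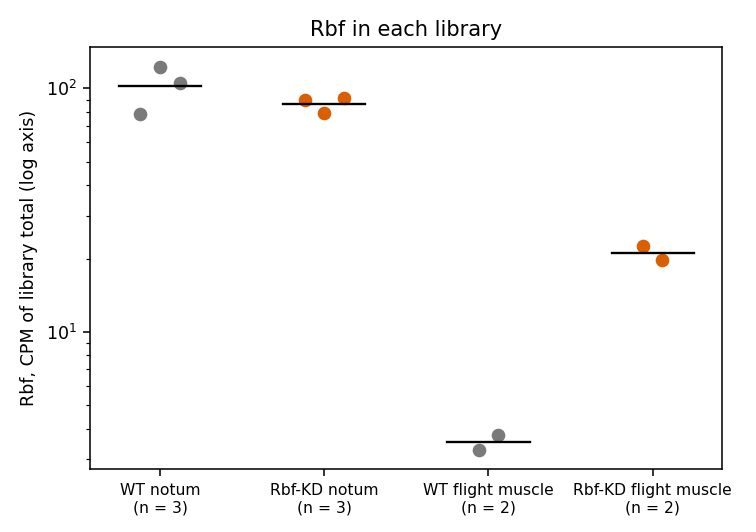
Rbf in each of the 10 libraries, as CPM of the library total on a log axis, with a line at the mean of each group (n = 3 for notum, n = 2 for flight muscle). In flight muscle both libraries labelled Rbf-KD (22.5 and 19.8 CPM) lie above both WT libraries (3.27 and 3.76 CPM), while in notum the groups overlap.

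The genotypes were compared in notum, where the Rbf hairpin is driven in the proliferating muscle precursors. These libraries also hold disc epithelium, outside the muscle lineage in which the driver acts. RNA of such cells can mask a knockdown or a response of the precursors. Few genes differed: 9 of 12203 were higher and 10 lower in the libraries labelled Rbf-KD. The gene mthl8 (3L), a methuselah-like receptor gene, was read almost exclusively in the libraries labelled Rbf-KD, with 1136, 1560 and 1524 counts against 0, 0 and 1 in WT (ratio of normalised counts 4149, 95% interval 744 to 163928, edgeR adjusted p = 1.91e-04). Lower in those libraries were Dscam4 (3L), a Dscam-family cell adhesion gene (log2 -2.41, SE 0.24, edgeR adjusted p = 0.0224), NaPi-III (3L), named as a phosphate transporter (log2 -2.02, SE 0.16, adjusted p = 0.0113), and Syt4 (3R), a synaptotagmin (log2 -1.31, SE 0.09, adjusted p = 0.00783). NaPi-III was at 124 ± 1.10 CPM in WT and 30.5 ± 6.30 CPM in the libraries labelled Rbf-KD (n = 3 each), and Syt4 at 101 ± 8.83 against 40.5 ± 1.67 CPM. Smaller decreases were found for Rnf11 (chromosome 4, log2 -0.92) and mthl4 (2R, log2 -0.91), and smaller increases for pst (3L, 0.87), rpk (3R, 0.85) and pinta (3R, 0.84). The overlapping genes p24-2 and Unc-115b hold identical counts (log2 1.08, adjusted p = 0.0161), and which of them rose is uncertain. E2f1 (-0.04), E2f2 (0.05), Dp (0.09) and Mef2 (0.04) did not pass the test.

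By edgeR no member of the 26 gene lists was called in notum, either over all genes or adjusted over the list alone. Of 427 members 23 had an unadjusted p under 0.05, limma-voom called 0, DESeq2 called 4 (Eno, mre11, ox and Psf1) and the replicate block 3 (e, Hr3 and y), these genes being named after their values were seen. By camera, Glycolysis was shifted down, with a median log2 fold change of -0.19 over 14 members (adjusted p = 3.82e-04, adjusted p = 0.259 with an estimated correlation). Its members of smallest p were Eno (-0.34, overlapping Rrp40 and so uncertain), Pfk (-0.27) and Pglym78 (-0.23, overlapping eIF2D). Mitosis was shifted down by a median of -0.06 over 41 members (adjusted p = 0.0146, adjusted p = 0.898 with an estimated correlation), with pav at -0.27, SMC2 at -0.26 and Bub3, which overlaps ppk19, at -0.22, none called. DNA replication genes had a median of 0.01 over 47 members. With the replicate block, Ecdysone response (adjusted p = 0.00383), Myoblast fusion (0.0340) and Myogenic regulators (0.0393) also passed, all upward, and with the block and an estimated correlation Glycolysis, Mitosis, Ecdysone response and Myogenic regulators gave adjusted p = 0.669 and Myoblast fusion did not pass. Both replicate 1 libraries stood apart on the first principal component (-44.0 and -48.3, against 5.99 to 31.7 for the others). Without them Glycolysis had an adjusted p of 0.0680 and Mitosis of 0.340, while 21 genes were higher and 19 lower. With fry, which tests a list against no change, Glycolysis had an adjusted p of 0.0533 and Mitosis of 0.964. Glycolysis was also lost without Rbf-KD replicate 1 (adjusted p = 0.0615), and Mitosis without WT replicate 1 (0.213), Rbf-KD replicate 1 (0.228) or Rbf-KD replicate 2 (0.331). The median, mean and camera direction differed in sign for Adult muscle precursors, Cuticle and pigment, DNA repair, DNA replication, Sarcomere and TCA cycle, none of which passed. Fat body markers had a median of -0.36 (camera adjusted p = 0.364), but passed downward without WT replicate 2 (7.28e-04) or Rbf-KD replicate 3 (0.0451). Other lists also passed with 1 library left out. Without WT replicate 2 these were Disc epithelium (7.28e-04), Myoblast fusion (7.28e-04), Myogenic regulators (0.0410) and Tendon cells (0.00636), all upward. Without WT replicate 3 they were Oxidative phosphorylation (0.0247) and Ribosome biogenesis (0.00680), both downward, without Rbf-KD replicate 1 Myoblast fusion (0.0152, upward) and without Rbf-KD replicate 3 Sex markers (0.0338, downward).

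The number of genes called in notum depended on the test and on single libraries. At an unadjusted edgeR p under 0.05 there were 496 of 12203 genes, no more than expected at that threshold with no effect. The replicate block gave 38 higher and 41 lower, and DESeq2 gave 60 higher and 70 lower. In simulated data of this design DESeq2 made 54 false calls against 11 by edgeR. DESeq2 recovered 87% of all 200 changed genes there, and edgeR 63% and 84% of those changed by 1 and by 2. Higher and lower counts were 1 and 2 without WT replicate 2, 1 and 1 without WT replicate 3, 5 and 8 without Rbf-KD replicate 1, 2 and 2 without Rbf-KD replicate 2, and 1 and 0 without Rbf-KD replicate 3. Among the named genes mthl8 passed in each of these, and every other named call was lost in at least 2 of them. In the fit of all 10 libraries Dscam4 (edgeR adjusted p = 0.0636), mthl4 (0.0690), rpk (0.0848), Rnf11 (0.100), pst (0.123) and pinta (0.463) did not pass. The calls of mthl8, NaPi-III, Syt4, p24-2 and Unc-115b held there. Dscam4 was also lost with the sum over transcripts (0.0532), and pst under library-total scaling (0.0664).

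In flight muscle the question was whether the hairpin alters the mature muscle. Here 2125 of 10930 genes were higher and 2223 lower in the libraries labelled Rbf-KD, in which the Rbf count itself was higher. With an estimated correlation the list test had 2 residual degrees of freedom here, and no list passed. DNA replication genes rose by list (adjusted p = 0.288 with an estimated correlation), and Glycolysis (adjusted p = 0.348 with an estimated correlation), Oxidative phosphorylation and TCA cycle (adjusted p = 0.474 with an estimated correlation for each) fell. Sarcomere genes fell on the TMM scale (adjusted p = 0.257 with an estimated correlation) but had a median of 0.02 under library-total scaling, and Fat body markers rose beside all of these (median 3.67, adjusted p = 0.221 with an estimated correlation). Under library-total scaling the median of all genes moved by 1.11 on the log2 scale, with 7449 genes higher and 554 lower, so all changes are relative to the typical gene on the TMM scale. Single libraries also moved the counts: 1189 genes were higher without WT replicate 1, 1303 without WT replicate 2, 1111 without Rbf-KD replicate 1 and 1271 without Rbf-KD replicate 2, while 1285 were lower without Rbf-KD replicate 1 and 1386 without Rbf-KD replicate 2.

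Genes of the cell cycle increased as a group, as did fat body markers and ribosome biogenesis genes. Of 47 DNA replication genes, 39 were higher and 0 lower in the flight muscle libraries labelled Rbf-KD (adjusted over the list alone, 41 higher and 1 lower), with a median log2 fold change of 3.42 (camera adjusted p = 1.50e-43, adjusted p = 0.288 with an estimated correlation). PCNA, the polymerase sliding clamp, was at 0.565 ± 0.0541 CPM in WT and 22.2 ± 1.48 CPM in the libraries labelled Rbf-KD (n = 2 each; log2 5.29, SE 0.19, edgeR adjusted p = 3.96e-04). Mcm5, of the replicative helicase, rose by 5.15 (SE 0.18) and RnrS, a ribonucleotide reductase subunit, by 4.05 (SE 0.15). Of 38 Mitosis genes 26 were higher and 2 lower (adjusted over the list alone, 29 and 2), with a median of 2.14 (camera adjusted p = 1.95e-08, adjusted p = 0.288 with an estimated correlation). They included aurB (3.32) and borr (5.56) of the chromosomal passenger complex and the centromeric histone gene cid, with 3 counts in WT and 400 in the libraries labelled Rbf-KD (ratio 54.3, 95% interval 18.5 to 265). The kinesin genes Klp10A (-0.77) and cana (-0.87) were the members that fell, but came to 0.33 and 0.24 under library-total scaling. DNA repair genes were higher for 23 of 27 and lower for 0 (median 1.86, camera adjusted p = 1.09e-14, adjusted p = 0.221 with an estimated correlation). Among them were rad50 (4.28) and mre11 (5.80), the latter overlapping Osi21 and so uncertain. All 20 Ribosome biogenesis genes were higher (median 2.82, camera adjusted p = 1.13e-18, adjusted p = 0.348 with an estimated correlation), for example Polr1B (3.47) and Nnp-1 (2.67). Markers of fat body moved with these groups. All 8 were higher (median 3.67, camera adjusted p = 1.47e-21, adjusted p = 0.221 with an estimated correlation), and the larval serum protein gene Lsp2 went from 37.0 ± 2.08 to 472 ± 2.35 CPM (n = 2 each) and Fbp2 from 6.46 ± 0.279 to 108 ± 9.38 CPM. For DNA repair, Ribosome biogenesis and Fat body the counts adjusted over the list alone were the same.

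Rb/E2F and dREAM components went both ways in flight muscle. Rbf is itself a member of this list and was among the higher genes (log2 1.48), a value to which hairpin reads counted as Rbf may add. Of 13 members 8 were higher and 1 lower, also when adjusted over the list alone (median 0.94, camera adjusted p = 0.0367, adjusted p = 0.627 with an estimated correlation, and 0.0687 without Rbf-KD replicate 2). The repressor gene E2f2 rose by 0.94 (SE 0.15, edgeR adjusted p = 0.00717), the dimerization partner gene Dp by 0.56 (adjusted p = 0.0172) and mip120, a dREAM subunit gene, by 1.57. The call of Dp was lost without WT replicate 1 (adjusted p = 0.0638), without Rbf-KD replicate 1 (0.0672) and without Rbf-KD replicate 2 (0.0818). The activator gene E2f1 was lower on the TMM scale (log2 -1.02, SE 0.15, adjusted p = 0.00562) but at 0.09 under library-total scaling. Mef2, which encodes a muscle transcription factor, was lower at -0.80 (SE 0.12, adjusted p = 0.00575) but at 0.31 under library-total scaling. The Fat body median of 3.67 accompanied these changes as well.

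**Figure D2:**
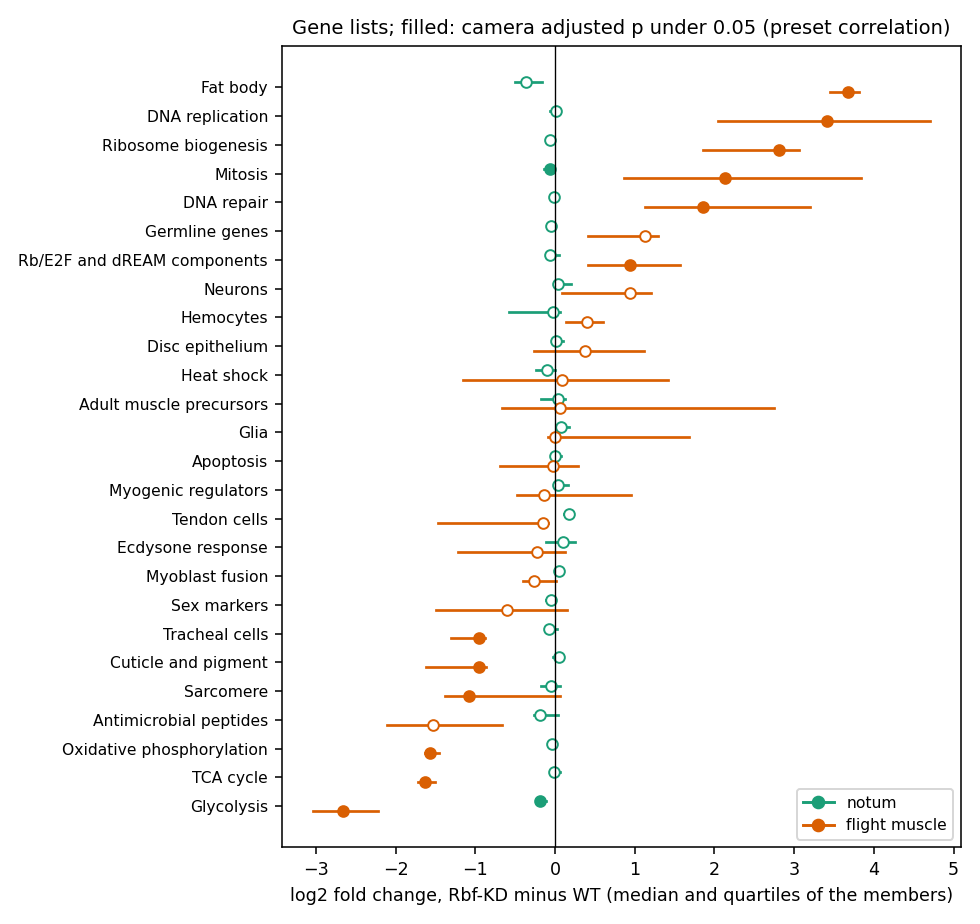
Median log2 fold change, labelled Rbf-KD minus WT, of the tested members of each gene list, with lines from the lower to the upper quartile, in notum (3 against 3 libraries) and flight muscle (2 against 2). Filled points passed camera at the preset correlation. In flight muscle Fat body (3.67) and DNA replication (3.42) lie farthest up and Glycolysis (-2.65) farthest down, while Sarcomere, Tracheal cells and Cuticle and pigment come to 0.02, 0.16 and 0.16 under library-total scaling.

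Energy metabolism moved the other way. Of 14 Glycolysis genes 13 were lower and 0 higher in the libraries labelled Rbf-KD (median -2.65, camera adjusted p = 4.89e-24, adjusted p = 0.348 with an estimated correlation). Pfk, which encodes phosphofructokinase, fell from 3336 ± 501 to 401 ± 32.3 CPM (n = 2 each; log2 -3.06, SE 0.17, edgeR adjusted p = 6.61e-04). Gpdh1, of the glycerol phosphate shuttle, changed by -3.19, and Eno, with the reservation on overlap given above, went from 6380 ± 705 to 799 ± 38.8 CPM. Of 40 Oxidative phosphorylation genes 39 were lower and 1 higher (median -1.57, camera adjusted p = 1.37e-23, adjusted p = 0.474 with an estimated correlation). The cytochrome c gene Cyt-c-p changed by -2.09, ATPsynCF6 by -1.70 and ox, which overlaps mRpL18, by -1.73, while COX7A was the member that rose (1.11). Of 16 TCA cycle genes 14 were lower and 1 higher (median -1.63, camera adjusted p = 1.08e-11, adjusted p = 0.474 with an estimated correlation), with the citrate synthase gene kdn at -2.51 and Idh3a at -1.78 against ScsbetaG at 1.22. In these 3 lists the counts adjusted over the list alone were the same, and the medians stayed below 0 under library-total scaling (-1.54, -0.45 and -0.52). The share of mitochondrial transcripts was lower in the same libraries, and the Fat body median was 3.67.

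Sarcomere genes fell for 26 of 45 members and rose for 3 (adjusted over the list alone, 26 lower and 6 higher), with a median of -1.08 (camera adjusted p = 5.31e-07, adjusted p = 0.257 with an estimated correlation). The direction depended on the scale, since under library-total scaling 18 members were higher and 11 lower with a median of 0.02. Mhc, the muscle myosin heavy chain gene, was at 126769 ± 10146 CPM in WT and 23428 ± 289 CPM in the libraries labelled Rbf-KD (n = 2 each; log2 -2.44, SE 0.12, edgeR adjusted p = 5.77e-04). It stayed lower under library-total scaling (-1.33), and had an adjusted p of 0.0655 in the fit of all 10 libraries. The Z-disc gene Zasp67 changed by -1.94 and sals, an actin filament gene overlapping CG17230, by -2.11. The members that rose were Mp20 (1.90), Act57B (1.35) and the troponin C gene TpnC73F (1.33). Markers of other cells moved beside these. Of 7 Tracheal cells markers 5 fell and 0 rose, or 7 and 0 adjusted over the list alone (median -0.95, camera adjusted p = 9.13e-04, adjusted p = 0.288 with an estimated correlation), for example uif (-1.47, or -0.36 with adjusted p = 0.0588 under library-total scaling). Of 9 Cuticle and pigment genes 3 fell and 0 rose by both adjustments (median -0.95, camera adjusted p = 0.0315, adjusted p = 0.627 with an estimated correlation), with e at -3.27 and knk at -1.62. The call of knk was lost without WT replicate 1 (adjusted p = 0.130), Rbf-KD replicate 1 (0.106) or Rbf-KD replicate 2 (0.155) and under library-total scaling (-0.51, adjusted p = 0.330). The Cuticle and pigment call was lost without WT replicate 1 (adjusted p = 0.144) and without Rbf-KD replicate 2 (0.0780), and with fry (0.164). Both medians are the value of verm, which with serp is in both lists, and came to 0.16 under library-total scaling, and Fat body markers had a median of 3.67.

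**Figure D3:**
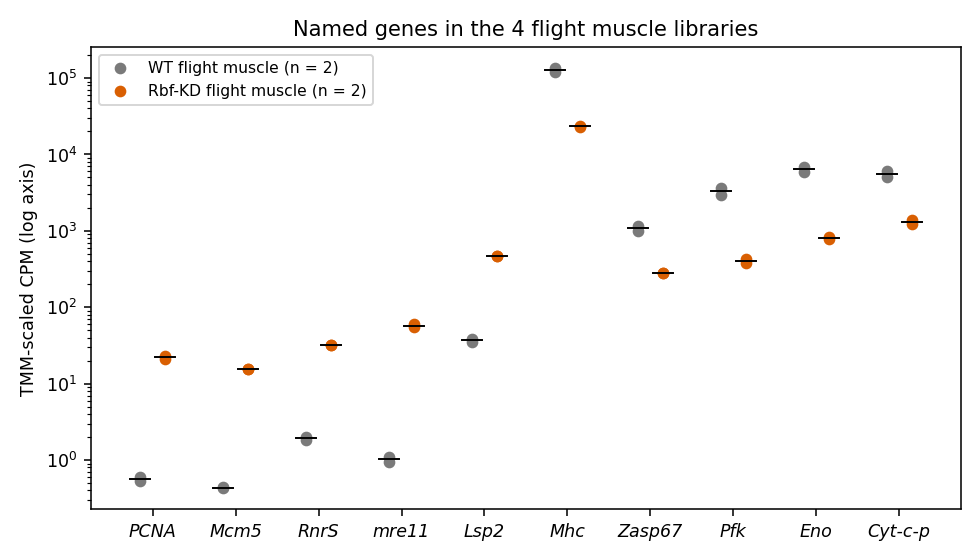
Named genes in the 4 flight muscle libraries, as TMM-scaled CPM on a log axis, with each library as a point and the group mean as a line (n = 2 per group). PCNA, Mcm5, RnrS, mre11 and Lsp2 were higher in both libraries labelled Rbf-KD, and Mhc, Zasp67, Pfk, Eno and Cyt-c-p were lower.

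The remaining lists did not pass camera in flight muscle. Of 10 Adult muscle precursors markers 4 were higher and 3 lower (median 0.06, adjusted p = 0.525), with the immunoglobulin-domain gene Ama at 3.79. Of 15 Myogenic regulators 2 were higher and 5 lower (median -0.13, mean 0.11, adjusted p = 0.501), and of 18 Myoblast fusion genes 0 and 4 (median -0.26, adjusted p = 0.169), with lmd, a member of both lists, at -3.99. Apoptosis genes were higher for 2 and lower for 4 of 13 (median -0.03, adjusted p = 0.411), with Buffy at -1.65 and hid at -1.54 (-0.54 and -0.43 under library-total scaling, where hid did not pass, adjusted p = 0.111). Ecdysone response genes were lower for 5 of 14 and higher for 0 (median -0.23, adjusted p = 0.161), with Eip74EF at -1.24 and Eip75B at -1.33 (-0.14 and -0.23 under library-total scaling, where neither passed, adjusted p = 0.438 and 0.268). Germline genes were higher for 2 and lower for 0 of 7 (median 1.13, adjusted p = 0.141), with the piRNA pathway gene spn-E at 3.36. Hemocytes markers were higher for 3 and lower for 0 of 13 (median 0.40, adjusted p = 0.276), and Disc epithelium markers higher for 0 and lower for 1 of 18 (median 0.38, adjusted p = 0.873). Neurons (median 0.94 over 10, adjusted p = 0.420) and Glia (median 0.00 over 5, adjusted p = 0.791) had 0 called members. Tendon cells had 1 higher and 2 lower of 5 (median -0.15, adjusted p = 0.627), Heat shock 1 and 0 of 10 (median 0.09, adjusted p = 0.783), Antimicrobial peptides 0 and 1 of 8 (median -1.52, adjusted p = 0.196) and Sex markers 0 and 2 of 4 (median -0.60, adjusted p = 0.411). Without WT replicate 2, Antimicrobial peptides (0.0301), Ecdysone response (0.0177) and Myoblast fusion (0.0168) passed downward, and without Rbf-KD replicate 1 Neurons (0.00320) passed upward. Adjusted over the list alone, Adult muscle precursors had 4 higher and 4 lower and Myogenic regulators 2 and 6, while the other counts of these lists were the same. Under library-total scaling the medians of Myogenic regulators (0.98), Myoblast fusion (0.84), Apoptosis (1.08), Ecdysone response (0.86), Tendon cells (0.94) and Sex markers (0.50) were positive.

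The genes with the largest single increases in flight muscle labelled Rbf-KD included the cytochrome P450 gene Cyp4p2 (2R, log2 7.94, SE 0.28, edgeR adjusted p = 3.96e-04) and the DNA processing genes Dna2 (X, 6.96) and PolE2 (3L, 6.80). BthD (X, 7.27) overlaps tth on the other strand and is uncertain. Drsl3 (8.37, SE 1.83, adjusted p = 0.0474) and Pgant4 (6.72, SE 1.60, adjusted p = 0.0494) varied between the libraries labelled Rbf-KD (31.1 ± 33.9 and 9.91 ± 10.7 CPM, n = 2). Their calls were lost without WT replicate 1 (adjusted p = 0.0954 and 0.114) and without WT replicate 2 (0.0945 and 0.116), and also with limma-voom (0.317 and 0.338), with no filter (0.117 and 0.122) and with a mean of at least 5 CPM (0.0513 and 0.0525). The largest decreases were those of bumpel (3R, -4.98), the repressor gene Blimp-1 (3L, -4.83, SE 0.92, adjusted p = 0.0298), Sfp53D (2R, -4.80), the ETS repressor gene aop (2L, -4.66, overlapping CG15382), Cln3 (3L, -4.50), which encodes a lysosomal membrane protein, and Cyp4e3 (2L, -4.43). Blimp-1 was at 222 ± 14.9 CPM in WT and 7.75 ± 6.90 CPM in the libraries labelled Rbf-KD (n = 2 each), and had an adjusted p of 0.0721 with the replicate block and 0.0874 with no filter.

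WT flight muscle was compared with WT notum to describe maturation, in which stage and tissue cannot be separated. Of 13407 genes 4468 were higher and 5823 lower in flight muscle. The muscle gene fln had 1024654 counts in flight muscle and 9 in notum (log2 19.84, SE 0.36, edgeR adjusted p = 1.17e-09). TpnC4 (17.24), Scp1 (16.23), Mhc (16.08) and Mlc1 (15.65) followed, and the cuticle gene Ccp84Ae had 1 count in notum (ratio 102195, 95% interval 18338 to 4036840). Tom, a Bearded-family gene, was at least 1039-fold lower in flight muscle, where it had no count (3 counts over the group as the limit). On the same limit Wnt2 was at least 230-fold lower, E(spl)m6-BFM 167-fold, Ocho 161-fold and yellow-e2 158-fold. ImpE2 had 263380 counts in notum and 4 in flight muscle. Rbf was lower in flight muscle (log2 -2.12, SE 0.22, adjusted p = 2.28e-05), as was Dp (-1.08). Mef2 was higher (2.90, and 0.16 with adjusted p = 0.390 under library-total scaling), and so was E2f1 (0.64), which came to -2.11 under library-total scaling. E2f2 did not pass the test on the TMM scale (0.21), but passed upward with DESeq2 size factors (0.36, adjusted p = 0.00973), with DESeq2 (0.00255), and without WT notum replicate 1 (0.0438) or WT flight muscle replicate 1 (0.0281), and downward under library-total scaling (-2.55, adjusted p = 3.38e-08), and Dcr-2, expressed by the driver, was at 5.26.

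Sarcomere genes, energy genes and hemocyte markers were higher in WT flight muscle. Oxidative phosphorylation was higher for 39 and lower for 1 of 40 (median 5.94, camera adjusted p = 1.62e-64, adjusted p = 0.0382 with an estimated correlation), for example Cyt-c-p (8.71), ATPsynbeta (6.31) and COX6B (5.79, sharing reads with CG18809). Sarcomere was higher for 38 and lower for 3 of 45, or 38 and 4 adjusted over the list alone (median 7.31, camera adjusted p = 4.33e-16, adjusted p = 0.0202 with an estimated correlation), with Act88F at 15.30 and Actn, which shares reads with usp, at 6.39. Glycolysis was higher for 13 of 14 (median 5.94, camera adjusted p = 1.37e-21, adjusted p = 0.0382 with an estimated correlation), with Gpdh1 at 10.25, Pglym78 at 7.77 and Eno at 5.71, while Ldh was lower (-2.60). TCA cycle was higher for 14 and lower for 2 of 16 (median 6.63, adjusted p = 0.0423 with an estimated correlation), with Idh3a at 7.07 and Pdhb at 6.71. Hemocytes markers were higher for 11 and lower for 0 of 14 (median 2.29, camera adjusted p = 8.70e-04, adjusted p = 0.0382 with an estimated correlation), led by atilla (6.69) and Hml (6.05), but their median was -0.47 under library-total scaling.

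Proliferation genes and disc markers were lower in WT flight muscle. Mitosis was lower for 39 and higher for 0 of 41 (median -6.21, camera adjusted p = 2.69e-26, adjusted p = 0.0202 with an estimated correlation), with thr at -6.29 and Cap-D2 at -5.72, both overlapping other genes. The passenger complex gene Incenp had 3 counts in flight muscle and 31172 in notum (ratio 1204, 95% interval 412 to 5840). DNA repair was lower for 25 and higher for 0 of 27 (median -3.11, adjusted p = 0.0202 with an estimated correlation), with rad50 at -4.67 and grp, overlapping CR43669, at -5.58. DNA replication was lower for 44 and higher for 3 of 47 (median -3.69, camera adjusted p = 5.14e-15, adjusted p = 0.103 with an estimated correlation), with Mcm5 at -5.63, PCNA at -5.40 and RnrS at -4.10. Ribosome biogenesis was lower for 19 and higher for 0 of 20 (median -2.90, camera adjusted p = 2.72e-07, adjusted p = 0.267 with an estimated correlation), with nop5 at -3.69 and Nopp140, overlapping P5CDh1, at -3.35. Disc epithelium was lower for 18 of 19 (median -3.63, camera adjusted p = 5.04e-04, adjusted p = 0.552 with an estimated correlation), with en at -5.98 and Fas3 at -3.45. Germline genes were lower for 8 of 10 (median -3.26, or -2.55 with genes of few counts at their limit, camera adjusted p = 0.0235, adjusted p = 0.201 with an estimated correlation), with bgcn at -5.54 and spn-E at -2.68. Rb/E2F and dREAM components were lower for 9 and higher for 2 of 13 (median -1.33, camera adjusted p = 0.0235, adjusted p = 0.267 with an estimated correlation), with Caf1-55 at -4.27 and mip40 at -1.91. Except for Sarcomere, counts adjusted over the list alone were the same for every list named in this comparison. Library-total scaling moved the median of all genes by -2.75, with 1464 genes higher and 10235 lower, and DESeq2 size factors by 0.15.

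**Figure D4:**
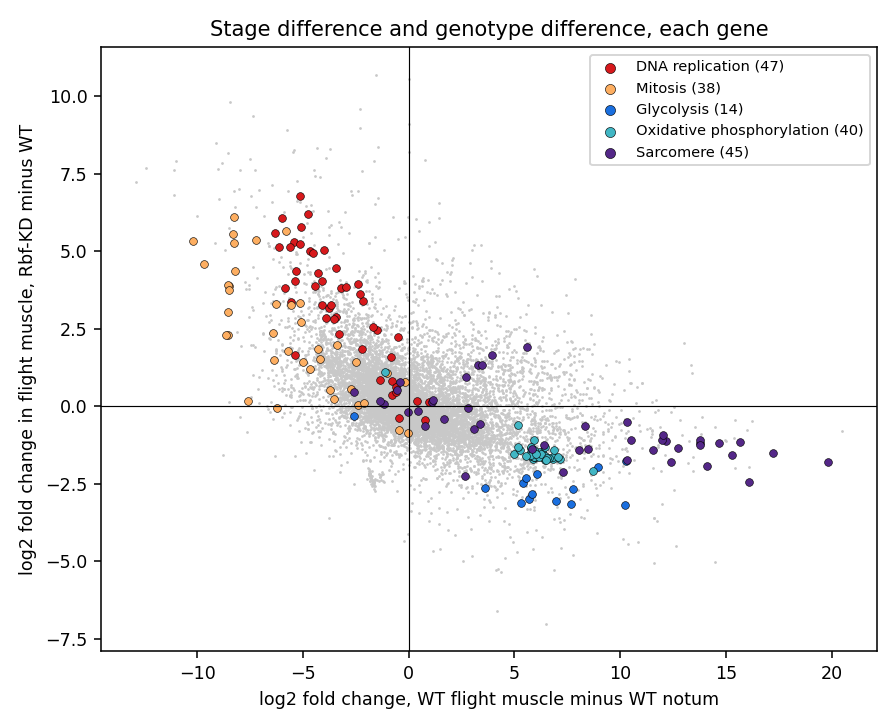
Each gene as a point, with the log2 fold change of WT flight muscle minus WT notum on the horizontal axis and that of flight muscle labelled Rbf-KD minus WT on the vertical axis, and members of 5 lists in colour. DNA replication genes (medians -3.69 and 3.42) lie in the upper left and Glycolysis genes (5.94 and -2.65) in the lower right. Sarcomere genes have medians of 7.31 and -1.08, the latter 0.02 under library-total scaling.

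The effect of genotype differed between the tissues for many genes, where the notum side is measured in precursors mixed with disc epithelium. Relative to notum, the effect in flight muscle labelled Rbf-KD, where Rbf was higher, was more positive for 2310 of 13407 genes and more negative for 1759. With DESeq2 size factors the counts were 1901 and 2256, and under library-total scaling 6989 and 365. DNA repair (median difference of the log2 fold changes 1.79), DNA replication (3.48), Mitosis (2.06) and Ribosome biogenesis (2.87) were more positive in flight muscle, and Glycolysis more negative (-2.45). With an estimated correlation these kept adjusted p = 0.00343, 0.00835, 0.0338, 0.0338 and 0.0300. The genes of smallest adjusted p were Mcm5 (5.12, SE 0.14, edgeR adjusted p = 5.81e-07), mre11 (5.47), Dna2 (6.95) and rad50 (4.30) in the positive direction. In the negative direction they were Orai (-3.50), a calcium channel gene, UGP (-2.81) and PGRP-LF (-2.43), which overlap each other, and Eno (-2.63).

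Oxidative phosphorylation (-1.49), TCA cycle (-1.62), Sarcomere (-0.75), Tracheal cells (-0.98), Cuticle and pigment (-0.98), Fat body (3.82) and Rb/E2F and dREAM components (0.92) also passed camera for the difference between tissues, though under library-total scaling Sarcomere came to 0.32 and Tracheal cells and Cuticle and pigment to 0.10. With an estimated correlation their values were adjusted p = 0.111, adjusted p = 0.111, adjusted p = 0.180, adjusted p = 0.236, adjusted p = 0.553, adjusted p = 0.534 and adjusted p = 0.219. Myoblast fusion had a median of -0.26 (0.82 under library-total scaling; adjusted p = 0.159) and passed with the replicate block (0.0438), without Rbf-KD notum replicate 1 (0.0458) and without WT flight muscle replicate 2 (0.0361). Germline genes (median 1.09, adjusted p = 0.0570) passed upward without WT notum replicate 2 (0.0491), Rbf-KD notum replicate 1 (0.0354), WT flight muscle replicate 1 (0.0464) or Rbf-KD flight muscle replicate 1 (0.0419). Heat shock passed upward without WT flight muscle replicate 1 (0.0105) and Ecdysone response (median -0.57, or 0.49 under library-total scaling) downward without WT flight muscle replicate 2 (0.0487). Counts over all genes, more positive and more negative, were 41 and 0 of 47 for DNA replication (42 and 1 adjusted over the list alone), 31 and 2 of 41 for Mitosis (32 and 2), 23 and 0 of 27 for DNA repair (24 and 0), 7 and 0 of 8 for Fat body (8 and 0), 0 and 3 of 7 for Tracheal cells (0 and 4) and 0 and 2 of 9 for Cuticle and pigment (0 and 3). They were 20 and 0 of 20 for Ribosome biogenesis, 0 and 13 of 14 for Glycolysis, 1 and 39 of 40 for Oxidative phosphorylation, 1 and 14 of 16 for TCA cycle, 3 and 11 of 45 for Sarcomere and 8 and 1 of 13 for Rb/E2F and dREAM components, with the same counts adjusted over the list alone. E2f1 differed by -0.96 (edgeR adjusted p = 0.00871), which came to 0.13 under library-total scaling, and E2f2 by 0.92 (7.93e-04). Mef2 (-0.81, or 0.26 under library-total scaling, adjusted p = 0.0740), Dp (0.49, adjusted p = 0.109) and Dcr-2 (-0.10) did not pass on the TMM scale. Under library-total scaling Dcr-2 (0.98, adjusted p = 0.00714) and Dp (1.56, adjusted p = 3.69e-05) passed upward. With the replicate block Mef2 (0.00747) and Dp (0.0427) passed, and Mef2 also did with DESeq2 (0.00382), with DESeq2 size factors (0.0267), with scaling without the 1% most abundant genes (0.0394), with a mean of at least 5 CPM (0.0287), without both replicate 1 notum libraries (0.0157) and without WT notum replicate 1 (0.0455), WT notum replicate 2 (0.00958) or Rbf-KD notum replicate 1 (0.0202). Without WT flight muscle replicate 1 or Rbf-KD flight muscle replicate 2 the Cuticle and pigment difference was lost (0.153 and 0.0830).

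Genes that separate the WT stages were then followed across genotypes. In flight muscle labelled Rbf-KD, of 2634 genes over 2 log2 units higher in WT flight muscle than in WT notum, 1240 were lower and 211 higher (median log2 fold change -0.59, camera p = 4.25e-20, p = 0.0839 with an estimated correlation). Of 1963 genes as much lower in WT flight muscle, 884 were higher and 28 lower (median 1.17, camera p = 1.75e-22, p = 0.0163 with an estimated correlation). These lists were chosen on the same WT libraries and are not independent evidence of direction. Library-total scaling moved the flight muscle fold changes up by a median of 1.11 on the log2 scale. The negative flight muscle medians given here may therefore turn positive on that scale, on which they were not computed. Fat body markers rose in the same libraries (median 3.67). In 20 simulations with no effect of genotype the medians averaged -0.02 and 0.05. Genes were simulated independently, so these values leave out deviations that genes of a library share. They cannot give the full size of the chance pull from the shared controls. With the stage difference taken from the libraries labelled Rbf-KD, which pulls the opposite way, the medians were -0.09 (camera p = 0.00143, p = 0.325 with an estimated correlation) and 0.31 (camera p = 0.326, p = 0.610 with an estimated correlation). With genes passing in both genotypes they were -0.37 and 0.59 (camera p = 0.162 and 0.203 with an estimated correlation). Those genes are still chosen in part on the WT libraries. In notum the medians were -0.02 and -0.03, against simulated means of 0.01 and -0.02.

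Calls were compared between the tissues, which share no libraries. Among 10268 genes tested in both, 5 were higher in the libraries labelled Rbf-KD in both tissues, against 1.56 for independent lists (one-sided Fisher's exact test, p = 0.00925). With genes of identical counts, such as p24-2 and Unc-115b, taken as 1, there were 4 against 1.37 (one-sided Fisher's exact test, p = 0.0306). Of the shared genes mthl8, p24-2 and Unc-115b are named above. The others were CG40470 and snoRNA:Psi28S-2949, named after their values were seen. Cyp6a17, Rnf11 and Syt4 were lower in both tissues, 3 genes against 1.88 (one-sided Fisher's exact test, p = 0.286), of which Cyp6a17 was also named after its values were seen. Genes are not independent replicates, so these tests describe the lists.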

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

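The tests of swapped labels, of hairpin reads, of Rbf against the replication genes, of scaling by the uncentred replication median and of dilution were chosen only after the result was seen. The differences of effect listed at the end passed a test of the difference between tissues itself (edgeR, or camera for lists), and the unmatched transcripts lie outside the gene comparisons.

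Rbf was higher in the flight muscle libraries labelled Rbf-KD and not in notum (difference 1.76). Swapped flight muscle labels were tested first by genes over 1 log2 unit apart in notum, of which 8 of 11 kept their sign in flight muscle (p24-2 and Unc-115b, with identical counts, both entered), short of the bound set and so undecided. Of the 7 that were also called in flight muscle 6 kept their sign, and NaPi-III reversed. By mthl8, read in notum in the Rbf-KD label almost alone and used after that bound was missed, all 4 flight muscle libraries split as their labels say, which argues against a swap of the flight muscle labels alone. Reads of the hairpin counted as Rbf may add to the value, but Rbf has 1 transcript in the table and the counts cannot show it. A rise of Rbf with the DNA replication genes also stays open, since its 1.48 lies under their lower quartile of 2.04 but above 9 of the 47 members.

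DNA replication genes were higher in flight muscle labelled Rbf-KD (adjusted p = 0.288 with an estimated correlation). The distance to the median of all genes (at least 3.32) cannot test the scaling, which moves both, but the list median itself was at least 3.37 under each of 4 scalings, so these are unlikely as the whole cause. Leftover notum-like cells would raise disc markers alike, but on the TMM scale these gained a median of 1.81% of their notum level (quartiles -0.911 and 7.03) against 65.4% for replication genes. Adult muscle precursors markers went both ways (median 1.96%, quartiles -25.8 and 21.5) and decide nothing about leftover precursors. These shares depend on the scale between tissues. They were not computed under library-total scaling, which moved WT flight muscle against WT notum by a median of -2.75 (log2). A general shift toward the whole WT notum profile also falls short. Other genes lower in WT flight muscle had an upper quartile of 1.87 against a replication median of 3.42. Such genes matched on the stage difference had 2.28, against a median of 3.99 for replication genes that are lower there. Notum also holds disc epithelium, whose genes need not rise in muscle. These values therefore cannot decide on a shift toward the precursor state. RNA of fat body cells stays open, as all 8 markers rose and Lsp2 reached 472 CPM with no fat body library for comparison, as does the genotype itself, which is confounded with the stocks.

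Glycolysis and Sarcomere genes were lower in flight muscle labelled Rbf-KD (adjusted p = 0.348 and adjusted p = 0.257 with an estimated correlation). Dilution by RNA of cells that express neither list would lower both alike. This was examined among genes over 2 log2 units higher in WT flight muscle than in WT notum. There Glycolysis had a median of -2.67 (n = 13) and Sarcomere of -1.17 (n = 34). The difference was -1.49 (permutation p = 1.00e-05, the smallest that the resamples can give). That permutation takes genes as independent, with an estimated correlation of 0.949 in Glycolysis, so its p does not measure the spread between samples. The difference makes such dilution unlikely as the whole cause. It cannot decide on cells with sarcomere RNA of their own. The fall of Glycolysis held under library-total scaling (-1.54), while that of Sarcomere did not (0.0245) and may come from the scaling. No biological explanation beyond the genotype label was tested.

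In notum 19 genes were called. Of the 10 splits of the 6 libraries 1 gave as many, the real one, and the highest of the others gave 0 by edgeR, but 3 against 3 libraries make too few splits for a share under 0.05. The split that sets WT 1, WT 3 and Rbf-KD 1 against the rest had 3157 genes at an unadjusted p under 0.05, against 496 for the real split, which points to a structure of the samples. Among the 4 splits that part all 3 pairs, the blocked count was 79 for the real split and at most 0 for the others.

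Differences of effect (flight muscle minus notum, edgeR adjusted p from 5.81e-07 to 0.0349) were positive for these genes: Dscam4 1.77, E2f2 0.92, NaPi-III 3.32, pav 4.93, SMC2 2.99, aurB 3.34, borr 5.72, BthD 7.29, cid 5.64 (a fitted value, on 3 counts in WT flight muscle), Dna2 6.95, Drsl3 8.38, Fbp2 4.26, Lsp2 3.63, Mcm5 5.12, mip120 1.54, mre11 5.47, Nnp-1 2.73, PCNA 5.41, Pgant4 6.15, PolE2 6.71, Polr1B 3.55, rad50 4.30 and RnrS 4.09. They were negative for E2f1 -0.96 (0.13 under library-total scaling), Eno -2.63, Pfk -2.76, Pglym78 -2.41, pst -1.10, Syt4 -1.28, aop -4.73, ATPsynCF6 -1.72, Blimp-1 -4.98, btl -1.88 (uncertain), bumpel -4.78, Cln3 -5.50, Cyp4e3 -4.72, Cyt-c-p -2.02, e -3.92, Gpdh1 -3.01, Idh3a -1.69, kdn -2.52, knk -1.62, ox -1.28, sals -2.25, Sfp53D -4.25, uif -1.36 and Zasp67 -2.07. Both lists of genes include those reported as uncertain for overlap.

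By list the median differences were 3.48 for DNA replication, 2.06 for Mitosis, 1.79 for DNA repair, 2.87 for Ribosome biogenesis, 3.82 for Fat body and 0.92 for Rb/E2F and dREAM components. They were -2.45 for Glycolysis, -1.49 for Oxidative phosphorylation, -1.62 for TCA cycle, -0.75 for Sarcomere (0.32 under library-total scaling) and -0.98 for both Tracheal cells and Cuticle and pigment (0.10 under library-total scaling). With an estimated correlation the call was lost for Fat body (adjusted p = 0.534), Rb/E2F and dREAM components (0.219), Oxidative phosphorylation and TCA cycle (0.111 each), Sarcomere (0.180), Tracheal cells (0.236) and Cuticle and pigment (0.553). Of 1708 unmatched transcripts tested in flight muscle, 267 were higher and 404 lower in the libraries labelled Rbf-KD, against 1 and 1 of 1767 in notum.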

How the results depend on the processing

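Leaving out both replicate 1 notum libraries, taking genes of identical counts as 1, the sum over transcripts, unmatched transcripts added, and the added blocks were chosen only after the result was seen. In notum, higher and lower genes numbered 60 and 70 with DESeq2, 38 and 41 with the replicate block and 21 and 19 without both replicate 1 libraries, each keeping all 9 and 10 genes of the main test. With an absolute log2 fold change over 1, 4 genes were higher. Leaving out single libraries gave 1 to 8 higher and 0 to 10 lower. In flight muscle, library-total scaling gave 7449 higher and 554 lower, a log2 fold change over 1 left 1247 lower, and leaving out single libraries gave 1111 to 1303 higher and 1285 to 1742 lower, where the lone library of a group is assumed to vary like the others. Fewer samples were fitted in these. For the stages, library-total scaling gave 1464 higher and 10235 lower. For the difference between tissues it gave 6989 and 365, while DESeq2 gave 2651 lower and a log2 fold change over 1 left 1005 lower. Genes called in both tissues numbered 3 higher with a log2 fold change over 1, against 0.573 for independent lists. With DESeq2 they were 18 higher and 19 lower, against 10.6 and 15.1. With the replicate block they were 12 higher and 6 lower, against 5.48 and 6.87, so the lower genes shared no more than independent lists would. Genes lower in flight muscle by the stage difference of the libraries labelled Rbf-KD had a median of 0.31 and did not pass camera. Under library-total scaling the sign reversed in flight muscle for Dcr-2 (0.90), E2f1 (0.0936) and Mef2 (0.31), between stages for E2f1 (-2.11) and E2f2 (-2.55), and in the difference for Dcr-2 (0.98), E2f1 (0.13) and Mef2 (0.26, passing on neither scale). With fry, which tests a list against no change and not against other genes, Glycolysis (0.0533) and Mitosis (0.964) in notum and Cuticle and pigment (0.164) in flight muscle no longer passed. The other lists that passed camera in flight muscle also passed fry, with adjusted p from 0.00353 (Fat body) to 0.0453 (Rb/E2F and dREAM components). Lists that passed with fry and not with camera were Apoptosis (0.0216), Germline genes (0.0212), Hemocytes (0.0241) and Sex markers (0.00837) in flight muscle, and Adult muscle precursors (0.0494), Germline genes (6.81e-04) and Hemocytes (0.00530) in the difference. Between stages they were Adult muscle precursors (1.80e-04), Antimicrobial peptides (0.00235), Apoptosis (0.0159), Ecdysone response (0.0186), Fat body (0.00832), Myogenic regulators (0.00259), Neurons (0.00385), Sex markers (0.00330) and Tracheal cells (0.0444). Where no cause is named, the cause was not tested. Apart from reversals in which either fit made a call, single-gene results stayed on the same side of the threshold in 384 alternatives in notum, 752 in flight muscle, 1005 between stages and 295 in the difference. Results called in neither fit were counted there whatever their direction, as was Mef2 in the difference. With the direction kept, calls were lost in 52, 21, 1 and 0 alternatives and gained in 1, 0, 4 and 11. For lists, counted in the same way, these numbers were 261, 158, 324 and 317 on the same side, 12, 16, 5 and 9 lost, and 13, 8, 9 and 12 gained. Depth limits genes with 0 counts to between 0.0409 and 0.0713 CPM.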

Other observations

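No further explanation was tested here. Lists that did not pass camera between the WT stages nevertheless held members that were called. Adult muscle precursors markers were higher in flight muscle for 4 and lower for 6 of 11 (median -2.30, adjusted p = 0.126), Neurons for 7 and 1 of 10 (median 2.35, or -0.41 under library-total scaling, adjusted p = 0.613) and Ecdysone response for 7 and 4 of 15 (median 0.49, mean -0.14, or a median of -2.26 under library-total scaling, adjusted p = 0.752). Fat body markers were higher for 2 and lower for 0 of 8 (median 1.15, or -1.64 under library-total scaling, adjusted p = 0.564).

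The genes mthl8, Cyp6a17 and v differed widely between the genotypes in notum and were chosen after their values were seen, and whether they mark the stocks or follow the hairpin was not tested. The gene mthl8 had 0 and 0 counts in WT flight muscle and 275 and 310 in flight muscle labelled Rbf-KD, at least 79.5-fold higher (3 counts over the group as the limit). Cyp6a17, a cytochrome P450 gene, had 341, 259 and 221 counts in WT notum and 2, 0 and 0 in notum labelled Rbf-KD. In flight muscle Cyp6a17 had 205 and 179 against 76 and 58 counts. The eye pigment gene v had 251, 157 and 185 counts in WT notum and 8, 6 and 7 in notum labelled Rbf-KD (log2 -4.80, edgeR adjusted p = 0.00558), against 29 and 29 and then 91 and 102 counts in flight muscle (log2 0.45, adjusted p = 0.344).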
